A study of Caenorhabditis elegans with 2 samples.

How the data were processed

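ChIP-seq peak lists of 1 group, late embryos of mixed sex at 5 hours after egg bleaching, were analysed from 2 biological replicates, which the labels number 2 and 3. Per the labels, chromatin was sonicated to 200 to 800 bp and precipitated with an antibody against GFP from worms expressing tagged CEH-19. The deposited files are narrowPeak lists on the ce11 build. Per the text files deposited with them, each replicate list holds peaks and background regions called on the alignments of that library with 1 control file, the pooled list was called on both libraries together, and the reproducible list derives from the others by the irreproducible discovery rate (IDR). The aligner, the peak caller, their versions, any read filter and the IDR threshold were not given in the sources used here. The signal value of each region is as the authors' peak caller wrote it, with no normalization stated, and was used to rank regions within a list and to compare the same peaks between the replicates. The deposited −log10 q-value of each region ran from 2.40 to 2.71 in the reproducible list and was not used in a test. All 1112 reproducible peaks were checked to be the 1112 strongest of the 30000 pooled regions. Neither read counts nor coverage were analysed here, so the depth is unknown. Intervals of shares are exact (Clopper-Pearson) at 95% and cover counting error only.

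Chromosome names and lengths of ce11 were checked against the reference assembly used here, the same build under its Ensembl name, and every region lay within them. Genes, exons and UTRs came from the Ensembl annotation, and tRNA names and amino acids from the RefSeq annotation, matched by gene identifier for 607 of 612 nuclear tRNA genes. Summits were the authors' positions. Peaks on the mitochondrial genome were kept in the comparisons between the replicates and left out of all others. A promoter ran from 500 bp upstream to 100 bp downstream of a protein-coding gene's 5' end, and a peak was assigned to the protein-coding gene with the nearest 5' end within 1 kb. Background regions were the lowest-ranked nuclear regions of the pooled list that overlap no reproducible peak, as many as there are peaks, and seeded random positions with the same number per chromosome.

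Peaks of different lists were matched by summits within 100 bp. Shares were compared with two-sided Fisher's exact tests, numbers by chromosome with exact two-sided binomial tests, and words at summits with the exact two-sided McNemar test against a window of the same width 300 bp to the left (odd ranks) or right (even ranks). Gene lists were tested with Fisher's exact test over 19973 protein-coding genes with Benjamini-Hochberg adjustment over 17 lists. Shares by location were adjusted over 14 tests, those by chromosome over 15 and words over 4 (fixed words, GAGAG among them), 10 (held-out words) or 16 (fixed words by peak class, chosen after the values were seen). Of the list members, 2 were not found in the annotation by name. Peaks of 1 pair of libraries are the units of these tests, so p-values describe these lists and not the spread over further cultures. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

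Named genes followed a rule fixed before the data were examined: the nearest protein-coding gene of the 25 strongest reproducible peaks with a 5' end within 1 kb, ceh-19 and unc-119 in any case, the 4 members of each gene list with the strongest reproducible peak, all members of the pharyngeal neuromuscular signalling list, and the strongest peak on each chromosome. Designs, gene lists and 53 alternatives were also fixed then. They change the matching distance, promoter and assignment windows, backgrounds, word windows and flanks, keep the stronger part of the peaks, or replace the reproducible list by the 1112 strongest regions of a single replicate ("without replicate 2" uses replicate 3 alone). The genes rpl-35 and rpl-7A, the pan-neuronal genes named without replicate 3, those along the stretch over ceh-19, rpr-1 and mir-51 fall outside the rule and were named after their values were seen. The comparisons of small RNA genes, the GAGAG alternatives, the summit-enriched words and all settings without peaks near small RNA genes were chosen after the values were seen.

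The statistics were tested on simulated data. For the overlap between replicates, 100% of 1000 summits moved by up to 50 bp were matched and 1.10% of unrelated ones. For the gene lists, members of the largest list, the 270 nuclear hormone receptors, were given extra peaks. That list was called in 100 of 100 repeats, and 0.25% of 1600 tests of the other lists were called. The planted effect was stronger than the odds ratio of any list in the real data at the main settings. Weaker effects and smaller lists were not tried, so the sensitivity for those is unknown. For the promoter share, 2 of 100 repeats with no planted difference were called, and moving some of 996 random positions to promoters raised the share from 11.0% to 29.0%. For the homeodomain motif, 1080 random positions gave an exact McNemar p of 0.736 before and 6.0e-55 after planting the word. In the search over all words the planted word ranked 1 and passed on held-out chromosomes, as did 2 of the 9 other chosen words. At the real summits, 225 of 226 words with at most 1 G or C were more frequent in flanks. Random positions lack that difference, so this simulation does not test false calls caused by base content.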

Results

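Chromatin precipitated through tagged CEH-19 was mapped in late embryos of the nematode Caenorhabditis elegans. No precipitation without the tagged protein was analysed here, so whether any peak depends on CEH-19 was not tested. CEH-19 is a homeodomain transcription factor known from a pharyngeal motor neuron class, MC, and a few other neurons. The worms carried an inserted transgene that makes CEH-19 fused to TY1, EGFP and 3xFLAG tags, and bound chromatin was precipitated with an antibody against GFP and sequenced (ChIP-seq). There was 1 group of 2 biological replicates, numbered 2 and 3, so no comparison between conditions was possible. Comparisons were made between the replicates, and between strong peaks and weak regions, genes or sequence of the same genome. The authors' list after their IDR threshold, called reproducible here, held 1112 peaks, of which 1091 lay on the 6 nuclear chromosomes. The replicate lists, which also hold background regions, had 30000 regions in replicate 2 and 29534 in replicate 3, and the pooled list had 30000. The read depth behind the lists was not given in the sources used here, so the precision of a single peak's signal value is known only from the spread between the replicates.

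The first comparison asked how far the replicates gave the same peaks. Of the 1112 reproducible peaks, 1039 had a summit within 100 bp of a region in replicate 2, 1080 in replicate 3, and 1011 in both. Among the 1112 strongest regions of both replicates were 595 of these peaks, and 55 were among those of neither. The peak upstream of K12H4.5 was the strongest nuclear peak of the reproducible list, by its pooled value, with signal values of 342 in replicate 2 and 796 in replicate 3. The peak in an intron of frm-7, beside the snoRNA genes C51F7.4 and C51F7.3, had 346 and 607, and that at the snoRNA gene W03C9.9 had 369 and 551, so both were the stronger ones in replicate 2. Across the 1011 peaks found in both, Spearman's rho was 0.519 (bootstrap 95% interval 0.466 to 0.570) and Pearson's r was 0.838, over peaks, which are not independent replicates. The log2 ratio of the signal value in replicate 3 to that in replicate 2 had a median of 0.553 over these peaks. Its SD was 0.546, a factor of 1.46. Of the 1112 strongest regions of replicate 2, 573 (51.5%, exact 95% interval 48.5 to 54.5%) lay within 100 bp of one of the 1112 strongest of replicate 3. In 100 random draws of as many regions from each full list, the median was 10 and the highest 19.

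**Figure D1:**
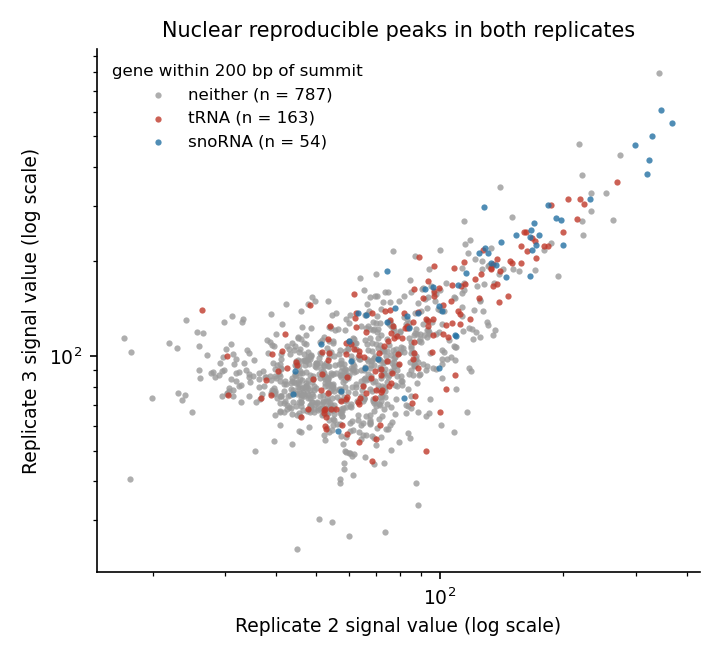
The signal value given by the authors for each nuclear reproducible peak found in both replicates, replicate 2 against replicate 3, both on log scales, coloured by a tRNA or snoRNA gene within 200 bp of the summit. Points at high signal lie close to a line, and those at low signal form a broad cloud.

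The second comparison asked where the peaks lie. Reproducible peaks lay mostly outside protein-coding genes, 716 of 1091 (65.6%) being intergenic, with 316 in introns and only 25 (2.29%) in coding exons. Promoters of protein-coding genes, taken as 500 bp upstream to 100 bp downstream of the 5' end, held 350 summits (32.1%, exact 95% interval 29.3 to 34.9%). Among the same number of lowest-ranked regions of the pooled list, 117 (10.7%) lay in promoters and 300 (27.5%) in coding exons, and random positions gave 112 promoter summits. The promoter difference had an odds ratio of 3.93 (95% interval 3.11 to 4.99, two-sided Fisher's exact test, p = 6.4e-35, adjusted p = 1.5e-34 over 14 tests of shares). The coding exon difference had one of 0.0618 (exact p = 7.1e-70, adjusted 1.0e-68).

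Genes of small non-coding RNAs were a second place of peaks. Summits lay within 200 bp of a tRNA gene at 168 peaks (15.4%, exact 95% interval 13.3 to 17.7%), of a gene of a small nucleolar RNA (snoRNA, a guide of rRNA modification) at 54 (4.95%), and of an snRNA gene at 10. The low-ranked regions had 1, 3 and 0 such summits, where a count of 0 allows up to 3, and random positions had 5 near tRNA genes. The odds ratio for tRNA genes was 198 (95% interval 34.9 to 7889, Fisher's exact p = 4.6e-52, adjusted 2.2e-51), a value that rests on 1 low-ranked summit. Against random positions it was 39.5 (16.5 to 123.7, exact p = 2.9e-46, adjusted 1.0e-45). For snoRNA genes it was 18.9 (6.09 to 94.6, exact p = 2.4e-13, adjusted 4.1e-13) against low-ranked regions. The snRNA difference had an exact p of 0.00191 (adjusted 0.00206). Of the 612 nuclear tRNA genes, 181 (29.6%) had a reproducible summit within 200 bp, as had 55 of the 346 snoRNA genes (15.9%). This class of genes and the distance of 200 bp were chosen after the values were seen. Each replicate alone gave a similar tRNA gene count among its 1112 strongest regions, 174 genes in replicate 2 and 164 in replicate 3.

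**Figure D2:**
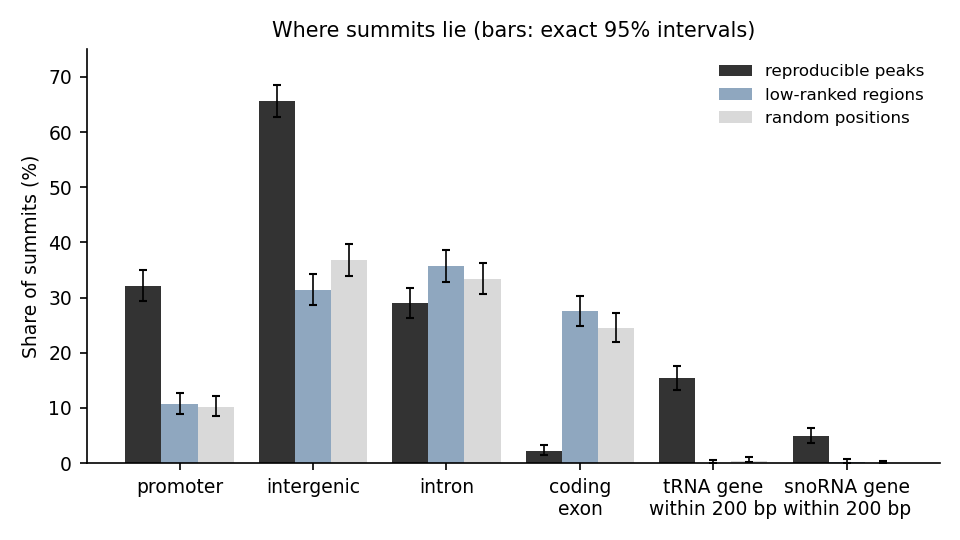
Share of summits (%) by location for the 1091 nuclear reproducible peaks, as many low-ranked pooled regions and as many random positions, with exact 95% intervals that cover counting error only. Promoter, tRNA and snoRNA shares are higher in the reproducible peaks (32.1, 15.4 and 4.95%) than in both other sets, and the coding exon share is lower.

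The strongest peaks by pooled signal value were described next, by chromosome. On III the strongest peak spanned 8043770 to 8044156 (ce11), in intergenic sequence at -524 bp from the 5' end of K12H4.5 (negative distances are upstream), with a pooled signal value of 1144. On V it was 12303440 to 12303825, in an intron of frm-7 at a pair of snoRNA genes (signal value 953). On II it was 11960646 to 11961023, intergenic at the snoRNA gene W03C9.9 (919). On IV it was 390351 to 390645, at -33 bp from ears-2, a glutamyl-tRNA synthetase gene (693), although in replicate 2 its signal value of 219 was below the 233 of a peak at mir-51. On I it was 8259396 to 8259740, intergenic at the snoRNA gene ZK265.10 and at -621 bp from sre-23, a chemoreceptor-family gene (690). On X it was 13665411 to 13665776, intergenic at the tRNA-Leu gene C04A11.t1 and 990 bp downstream of the 5' end of C04A11.5 (631).

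Of the 50 strongest nuclear peaks, 19 had a snoRNA gene and 15 a tRNA gene within 200 bp, and 35 had a small RNA gene of either kind or an snRNA gene. Of the 50, 25 had the 5' end of a protein-coding gene within 1 kb, and these 25 are the named set. In 13 of the 25 the summit also lay within 200 bp of a small RNA gene. Peaks beside tRNA genes were those assigned to C04A11.5, cye-1 (cyclin E), egl-17 (a fibroblast growth factor), C28G1.2, gcy-33 (a guanylate cyclase) and col-85 (a collagen). Peaks beside snoRNA genes were those of sre-23, Y43F8C.7, T02E1.2, cfim-2 (a pre-mRNA cleavage factor subunit), pdl-1, twk-5 (a potassium channel) and F55A11.11. The other 12 had no tRNA, snoRNA or snRNA gene that close. Among them, summits lay at -63 bp from the 5' end of atx-2 (an ataxin-2 homologue, signal value 594), -62 bp from that of idhg-1 (an isocitrate dehydrogenase subunit, 468), -68 bp from tasp-1 (432) and -37 bp from spe-48 (394). Farther upstream lay those of rpl-3 (a ribosomal protein, -270 bp, signal value 415), ftt-2 (a member of the 14-3-3 family, -514 bp, 505), eel-1 (a ubiquitin ligase, -556 bp, 382), T13C5.6 (-186 bp, 486), W01D2.3 (-218 bp, 379) and M01F1.9 (-968 bp, 716). The M01F1.9 summit lay in an intron of another protein-coding gene. Genes annotated as other non-coding RNAs lay within 200 bp of the ftt-2, T13C5.6 and W01D2.3 summits. The spread of a factor of 1.46 is that of the ratio between the replicates over all matched peaks, weak ones included. The error of the pooled signal values of these strong peaks was not estimated, so the order of peaks with like values is not taken as resolved.

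Strong and weak reproducible peaks were then compared for location. The weak ones were less often among the strongest regions of both replicates. In the strongest of 4 rank groups, 260 of 272 peaks (95.6%) were among the 1112 strongest regions of both replicates. In the weakest, 15 of 275 (5.45%) were. The weakest group lies next to the cut that ends the list, so part of this difference follows from the cut. How much of it does was not tested. Near tRNA genes lay 77 of the 272 strongest peaks (28.3%) and 20 of the 272 weakest (7.35%, odds ratio 4.98, two-sided Fisher's exact p = 1.2e-10, adjusted 1.7e-10). Near snoRNA genes lay 40 and 2 (odds ratio 23.3, 95% interval 5.90 to 200.2, exact p = 1.0e-10, adjusted 1.6e-10). Promoter shares of these peaks were 31.6% and 30.1% (odds ratio 1.07, 95% interval 0.732 to 1.57, exact p = 0.781, adjusted 0.781), a difference that was not detectable. With all peaks split at the median signal value instead, the odds ratio was 1.36 (exact p = 0.0231). Without the peaks near small RNA genes, an alternative chosen after the values were seen, 102 of the 214 strongest (47.7%) and 67 of the 214 weakest (31.3%) lay in promoters (odds ratio 2.00, exact p = 0.000751, adjusted 0.000876). With the 1112 strongest regions of replicate 2 alone, that is without replicate 3, the promoter shares were 36.9% and 21.9% (odds ratio 2.08, exact p = 0.000166, adjusted 0.000212).

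**Figure D3:**
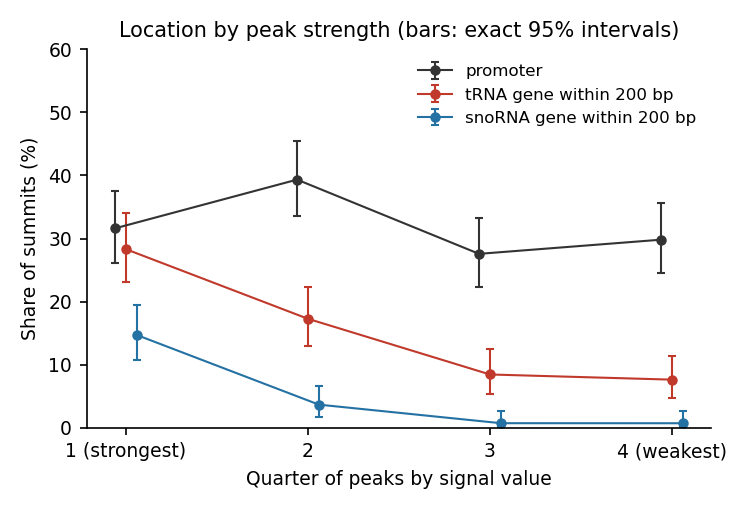
Share of summits (%) in promoters and within 200 bp of tRNA and snoRNA genes, for 4 consecutive rank groups of the nuclear reproducible peaks from the strongest to the weakest signal value, with exact 95% intervals that cover counting error only. The tRNA share goes from 28.3% to 7.64% and the snoRNA share from 14.7% to 0.727%, while the promoter share stays between 27.6% and 39.3%.

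The next comparison asked whether the peaks are spread over the chromosomes by length. Chromosome X held 285 of the 1091 nuclear peaks (26.1%, exact 95% interval 23.5 to 28.8%) on 17.7% of the sequence, 1.48 times the number by length (exact two-sided binomial test, p = 3.8e-12, adjusted p = 2.9e-11 over 15 such tests). Peak density was 16.1 per Mb on X, 12.5 on III, 12.3 on I, 10.3 on II, 8.29 on IV and 6.98 on V. Of the 285 peaks on X, 76 lay near tRNA genes, and X holds 276 of the 612 nuclear tRNA genes. Without tRNA-adjacent peaks, chosen after the values were seen, X held 209 of 923 peaks, 1.28 times the number by length (exact binomial p = 0.00012, adjusted 0.000163). On the autosomes, 471 of 806 peaks (58.4%, exact 95% interval 54.9 to 61.9%) lay in the middle 50% of the chromosome (exact binomial p = 1.9e-06, adjusted 3.1e-06). Protein-coding genes are themselves concentrated there, at 55.7%, and against that share the excess was not detectable (ratio 1.05, exact p = 0.119, adjusted 0.119). Of the low-ranked regions, 400 of 897 (44.6%) lay there, under 50% (exact binomial p = 0.00134, adjusted 0.00167).

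**Figure D4:**
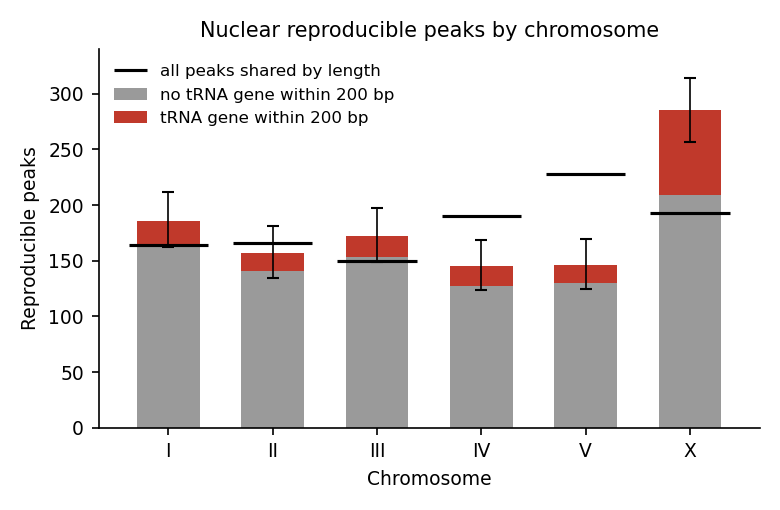
Number of nuclear reproducible peaks on each chromosome, split by a tRNA gene within 200 bp of the summit, with exact 95% binomial intervals and, as lines, the numbers by chromosome length. On X the 285 peaks lie above the 193 by length, and on V the 146 peaks lie below 228.

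The peaks were also set against 17 fixed gene lists for the pharynx, nervous system, other tissues and housekeeping functions. A reproducible peak had its nearest protein-coding 5' end within 1 kb at 494 of 19973 genes (2.47%). None of the 10 genes of pharyngeal neuromuscular signalling had such a peak. In the pooled list, eat-18, a protein needed for pharyngeal nicotinic receptors, had a region 47 bp downstream of its 5' end at rank 1987 of the nuclear regions, below the reproducible set. Regions of lower rank lay by cha-1 (5770), flp-2 (10685), ser-7 (12225), eat-2 (19287) and avr-15 (21130). The genes eat-4, flp-21, gar-3 and unc-17 had none within 1 kb. Over all 19973 genes, 8283 had a pooled region assigned this way, background regions included, so such regions are common. There was also no reproducible peak at the lists of pharynx regulators and muscle (0 of 13), acetylcholine and serotonin pathway (0 of 10), neuronal transcription factors (0 of 29), Hox genes (0 of 6), intestine (0 of 14), epidermis (0 of 17) and germline (0 of 18). Without replicate 3, 1 gene each of the pharynx regulators and muscle, the neuronal transcription factors and the epidermis list had a peak. At these sizes a depletion was not detectable; for the neuronal transcription factors the upper limit of the odds ratio was 5.36.

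Ribosomal protein genes had the smallest p, with peaks at 6 of 78: rpl-3, rps-24, rpl-15, rps-28, rpl-35 and rpl-7A (odds ratio 3.31, 95% interval 1.17 to 7.62, Fisher's exact p = 0.0127, adjusted p = 0.217), which did not pass adjustment. Of the pan-neuronal genes 2 of 19 had a peak, at -200 bp from rgef-1, a Ras exchange factor, and at -978 bp from egl-3, a neuropeptide convertase (exact p = 0.0792, adjusted 0.673). The other lists had peaks at 3 of 92 homeobox genes (ceh-38, ceh-2 and ceh-39), 5 of 270 nuclear hormone receptors (nhr-255, nhr-48, nhr-47 and nhr-35 the strongest), 3 of 72 histones (his-68, his-62 and his-24), 2 of 156 collagens (col-85 and col-185), 2 of 140 neuropeptide genes (nlp-4 and flp-23), 1 of 33 proteasome subunits (rpn-9) and 1 of 14 body wall muscle genes (act-4). The homeobox count was 1 without replicate 2 (odds ratio 0.429) and 5 without replicate 3 (odds ratio 2.38, adjusted exact p = 0.382, from 0.382 to 1 over the alternatives), so its direction is not settled. Without replicate 3 the neuropeptide count was 1 and the proteasome count 0. The 2 collagen and 2 neuropeptide gene peaks all lay within 200 bp of a tRNA or snoRNA gene, and without peaks near small RNA genes both counts were 0. With Fisher's exact test and Benjamini-Hochberg adjustment over the lists, 0 of 17 passed, and 1 had an unadjusted p under 0.05. The ribosomal proteins passed with either replicate alone, with 8 genes without replicate 2 (adjusted exact p = 0.0122) and 7 without replicate 3 (adjusted exact p = 0.0211). The pan-neuronal genes passed without replicate 3 with 5, rgef-1, unc-11, egl-21, ehs-1 and unc-10 (adjusted exact p = 0.0011), and not without replicate 2 (adjusted exact p = 0.0943). With only the peaks above the median signal value, 0 of the 19 pan-neuronal genes had one. Over the 8 alternatives, adjusted exact p ran from 0.00015 to 1 for the ribosomal proteins and from 0.0011 to 1 for the pan-neuronal genes.

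Sequence at the summits was compared with sequence 300 bp away, since homeodomain proteins commonly bind words with a TAAT core. TAATTG or TAATTA lay within 50 bp of the summit at 53 of 1091 peaks (4.86%) and in the flank window at 133 (12.2%), a depletion (exact two-sided McNemar test, p = 8.5e-10, adjusted over 4 words 1.1e-09). TAAT alone was found at 360 summits and 687 flanks (exact McNemar p = 2.0e-43, adjusted 7.9e-43). Low-ranked regions also had TAAT less often at summits, 612 against 681 flanks (exact McNemar p = 0.0024). For TAATTG or TAATTA they had 103 against 118 (exact McNemar p = 0.311). TAAACG, a word of BarH-type homeodomains, showed no detectable difference, 35 against 38 (exact McNemar p = 0.815, adjusted 0.815). Near snoRNA genes TAAACG lay at 8 of 54 summits and 1 flank (exact McNemar p = 0.0391, adjusted 0.0521 over 16 tests of words by peak class), which did not pass adjustment. GAGAG was enriched, at 459 summits (42.1%) against 188 flanks (17.2%, exact McNemar p = 1.5e-35, adjusted 3.0e-35), and low-ranked regions had it at 164 summits and 137 flanks (exact p = 0.103). GAGAG was more frequent at summits than flanks near tRNA genes (60 against 21 of 168 peaks), in promoters away from small RNA genes (109 against 47 of 319) and at the remaining peaks (271 against 105 of 540). Near snoRNA genes the counts were 17 and 11 of 54 (exact McNemar p = 0.238, adjusted 0.293).

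In a search over all 2080 words of 6 bases on chromosomes I, III and V, the 10 words with the smallest p all passed on chromosomes II, IV and X (exact McNemar test, largest adjusted p = 4.1e-08). The first of them was AAAAAT, and 9 of the 10 were rich in A and T and more frequent in flanks, such as AAAATT at 55 summits and 229 flanks of 587 peaks (adjusted exact p = 4.6e-30). The exception, ACACAC, was found at 100 summits and 32 flanks (adjusted exact p = 3.5e-10). Of the words chosen for enrichment at summits, a choice made after the values were seen, GAGAGA was found at 22.7% against 8.01% and CGTCTC at 14.7% against 3.24% on the held-out chromosomes (adjusted exact p = 1.9e-11 for both).

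The last comparison looked at the genes carried by the transgene, ceh-19 itself and the rescue marker unc-119. No reproducible peak lay within 20 kb of either, as in 68.7% of gene-centred windows. Around ceh-19, at 7953500 to 7955949 on the minus strand of IV, the pooled list and both replicate lists also held no region at all within 20 kb of the gene's middle, although these lists include background. The median gene-centred window held 11 pooled regions, and 1.93% of the 19973 windows held none (1.42% in replicate 2 and 0.881% in replicate 3). The rarity depends on the width. Within 10 kb, 6.83% of windows held no pooled region (6.05% in replicate 2 and 3.51% in replicate 3). Within 50 kb the ceh-19 window held 18 pooled regions, with 19.97% of windows as low. It held 12 regions in replicate 2 (9.03% of windows as low) and 24 in replicate 3 (33.1%). Windows without a region in any of the 3 lists numbered 89 (0.446%). The stretch without regions shared by the lists ran from 7926567 to 7977026, or 50.5 kb, and spanned 13 protein-coding genes, among them gcy-8, bbs-2, exc-9, czw-1, csr-1 and frpr-10. In the pooled list alone the stretch ran from 7926542 to 7982332, or 55.8 kb. Only 37 of the 29971 distances between neighbouring pooled regions were as long as that one, and the median was 1786 bp. The unc-119 window, at 10902641 to 10908935 on III, held 19 pooled regions, more than or as many as 91.1% of windows, and the strongest of those in the gene had rank 1814 of the pooled list.

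**Figure D5:**
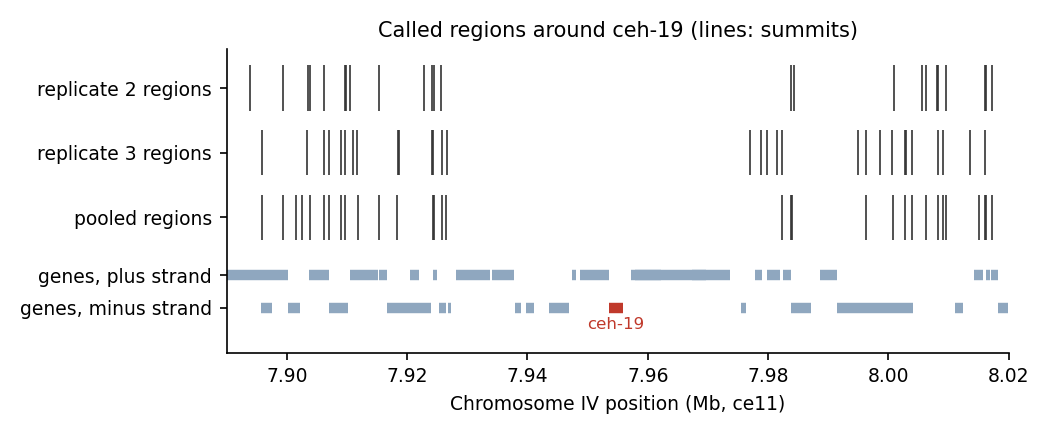
Summits of all regions in the replicate 2, replicate 3 and pooled lists on chromosome IV around ceh-19 (position in Mb, ce11), with protein-coding genes by strand. The lists share a stretch of 50.5 kb without any region, with ceh-19 inside it.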

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

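Peaks on the mitochondrial genome were left out of the comparisons of location, chromosomes, genes and sequence, and came to notice as a signal in data those did not use. The reproducible list held 21 of them on a genome of 13794 bp. They included the strongest peak of the list (signal value 1688) and 6 of the 10 strongest, and covered 45.6% of the mitochondrial sequence. The lists of replicates 2 and 3 held 15 and 24 mitochondrial regions. No explanation was tested.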

How the results depend on the processing

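Settings without peaks near small RNA genes, the tRNA and snoRNA results and all alternatives of the GAGAG result were chosen after the values were seen. Of 79 alternatives of the main results, 61 kept direction and side of the threshold, or stayed within the stated spread. The promoter, X chromosome, TAATTG or TAATTA, GAGAG, tRNA and snoRNA results kept theirs under every alternative run. The Spearman correlation between the replicates, across peaks, moved to 0.598 with summits within 50 bp, and Pearson's r of log2 values was 0.662. The overlap of the strongest regions was 38.3% within 50 bp, 60.7% within 200 bp, 63.2% by any interval overlap, 59.5% with the strongest 556 regions and 43.3% with double the main number. Reproducible peaks among the strongest of both replicates numbered 595, and those above the median signal value number 556 by construction. The odds ratio of promoter share by strength passed the threshold with peaks split at the median (1.36) and without peaks near small RNA genes (2.00), and was 1.17 without replicate 2 and 2.08, past it, without replicate 3. The ratio of chromosome centre peaks fell below the threshold against gene positions (1.05), since genes are concentrated there. The number of gene lists passing went from 0 to 1 with every gene within 1 kb, the ribosomal proteins, and to 1 to 2 without each replicate. The share of gene windows with as few regions as that of ceh-19 was 6.83% at 10 kb and 19.97% at 50 kb in the pooled list. At 20 kb it was 0.881 to 1.42% without each replicate. Of 72 alternatives for single gene lists, taken from the 9 lists with a member with a peak, 68 gave the same verdict and 4 became significant. Except where given, the cause was not tested. Unknown depth limits any reading of weak peaks.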

Other observations

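The tests of summit position along tRNA genes, of ribosomal protein genes, of windows matched on unique share, of promoters against GC-matched regions, of GA and CA repeats and of X without tRNA-adjacent peaks were chosen only after the results were seen. Peaks lay at tRNA genes of nearly every amino acid. Of 21 tRNA kinds, 20 had a gene with a reproducible summit within 200 bp, from 2 of 12 tRNA-Trp genes to 6 of 13 tRNA-Cys genes, 19 of 55 tRNA-Gly genes and 15 of 42 tRNA-Pro genes, and the exception was the single tRNA-Sec gene. The summits lay towards the 5' side: the median was -24.2 bp from the gene's middle, negative being upstream, in genes with a median length of 72 bp, and 111 of 168 summits were upstream (66.1%, exact binomial p = 3.8e-05). A peak of signal value 526 at rank 17 of the nuclear peaks lay at rpr-1, the RNA component of RNase P, which like tRNA genes is transcribed by RNA polymerase III, and one at rank 13 lay at the microRNA gene mir-51. Both were named after their values were seen.

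GC content does not account for the whole promoter excess, since low-ranked regions matched to the peaks on GC (47.6% in both) had 139 promoter summits (12.7%) against 350 (odds ratio 3.23, Fisher's exact p = 9.1e-28).

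Reads shared between near-identical copies do not account for all peaks at tRNA genes, since 8 of 56 tRNA genes in unique surroundings had a peak (14.3%, exact 95% interval 6.38 to 26.2%), but the share was higher, 173 of 556 (31.1%), where surroundings were less unique (Fisher's exact p = 0.00849), so copies may add to the count. GC-rich sequence does not account for them either, as 0.733% of the GC-matched regions lay near tRNA genes (exact p = 7.4e-43). High transcription in general stays open: within 200 bp, 2 of 78 ribosomal protein genes had a summit against 181 of 612 tRNA genes (exact p = 6.1e-09), but their peaks can lie farther upstream, as at rpl-3 (-270 bp). Within 1 kb, 12 of them (15.4%) had one, fewer than the 207 tRNA genes (33.8%, exact p = 0.000718), and a difference from the 10 of 56 tRNA genes in unique surroundings (17.9%) was not detectable (exact p = 0.814). Enrichment of polymerase III genes in any precipitation stays open as well, since no precipitation without the tagged protein was analysed here, and no biological explanation was tested.

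Reads that cannot be placed uniquely do not explain the stretch without regions over ceh-19, since the share of 32-base words found once in the genome, 92.9% in the window, was at percentile 39.3 of gene-centred windows. Windows of like GC content and at least 95% unique sequence were empty in all 3 lists in 2 of 5410 cases (0.0370%), 1 of them outside this stretch, so base content does not explain it either. That limit leaves out the ceh-19 window itself, and of 1987 windows of like GC content and like unique share 0 were empty (exact upper limit 0.185%). The 89 empty windows fall in 17 stretches, 12 of them on IV. That with the most windows, on V, had almost no unique sequence (0.658%). Still, 12 stretches were over 70% unique, 10 of them on IV with that of ceh-19 included. The others of these on IV had window centres between 13634315 and 16199381, away from those of the ceh-19 stretch (7947746 to 7954724). A candidate explanation is extra copies of the locus in the transgene, which could raise the control and the precipitate alike or lead to removal of the region. The window of unc-119, also carried by the transgene, was not empty, with 19 pooled regions, 18 in replicate 2 and 15 in replicate 3. Of the pooled regions, 5 lay in the gene itself. How much sequence around unc-119 the transgene carries was not examined, so these counts cannot decide on that explanation. No read density was analysed here to test the explanation by extra copies, and no biological explanation was tested.

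Fewer TAATTG and TAATTA words at summits are consistent with base content. Their log2 ratios of summit to flank presence, -1.25 and -1.50, were at percentiles 47.8 and 24.8 of 226 other words with at most 1 G or C, whose median was -1.22 and of which 225 were more frequent in flanks. The depletion therefore may say nothing about these words as such, and no enrichment of them was seen. No biological explanation was tested.

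GA and CA repeats at summits may go beyond base content. On chromosomes II, IV and X, which were not used to pick these words, GAGAGA and ACACAC had log2 ratios of 1.49 and 1.63, at percentiles 96.4 and 97.49 of 638 other words with 3 G or C. The median of those was 0.20 and their 95th percentile 1.38, so both words lay only a little above it.

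The concentration of tRNA genes on X was tested as a possible explanation of the excess of peaks there. It does not account for all of the excess over length, as the ratio without tRNA-adjacent peaks was 1.28 (exact binomial p = 0.00012). Peaks not near tRNA genes numbered 209 on X (17718942 bp), 163 on I (15072434 bp), 153 on III (13783801 bp) and 141 on II (15279421 bp). There were 127 on IV (17493829 bp) and 130 on V (20924180 bp), and these low counts add to the ratio of X. Whether X exceeds I or III without tRNA-adjacent peaks was not tested. A difference between tRNA genes on X and on autosomes in how often they had a peak was not detectable, with 82 of 276 (29.7%) against 99 of 336 (29.5%, odds ratio 1.01, 95% interval 0.703 to 1.46, Fisher's exact p = 1).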
